A study of Mus musculus with 6 samples.

How the data were processed

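RNA was measured in the RET line, a mouse melanoma cell line, carrying either a non-targeting short hairpin RNA (shRNA) or an shRNA against Angpt2. Per the labels, equal numbers of cells were seeded and cultured for 24 h before total RNA was isolated, and 100 ng of RNA per sample was amplified, labelled with biotin and hybridised to an Affymetrix Mouse Gene 2.0 ST array. Each of the 6 samples had its own array. The deposited values were intensity per transcript cluster on a linear scale, already normalized by the authors, and how they corrected background, summarized probes and normalized arrays is not given in the sources used here. The linear scale was read from the values, which ran from 28.1 to 12624 with array medians between 74.5 and 76.2.

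Groups were taken from the genotype labels, with 3 control shRNA samples and 3 Angpt2 shRNA-1 samples, each described in the labels as a biological replicate. The control titles also carry the word GFP, which was not interpreted. No pair of arrays held identical values. The correlation of log2 values between arrays of one group ranged from 0.983 to 0.993.

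Of 41345 transcript clusters, 40425 had a value on all 6 arrays, 725 were empty on all arrays and 195 on some. The platform annotation paired 23521 clusters with exactly 1 gene symbol and 1814 with several, and 16010 were unnamed here. Clusters with 1 symbol entered the gene-level test, and for the 1082 genes with more than 1 such cluster the cluster with the highest mean over the 6 arrays was used, which left 22180 genes. Gene IDs of 23328 of these clusters were present in the mouse RefSeq table used for names. The genome build behind the array annotation is not given in the sources used here, so no coordinates are printed. The table carries no detection calls, so low intensities could not be told from background. The number of arrays limits the precision.

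The values were converted to log2 without a pseudocount and without further normalization. Groups were compared with lmFit and eBayes in limma 3.58.1 (R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Adjusted p-values are from this fit unless another test is named. Fold changes are Angpt2 shRNA-1 relative to control shRNA and are ratios of geometric means. Exact permutation tests of single genes, which with 3 against 3 arrays cannot give a two-sided p below 0.1, were run beside it.

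Before the data were examined, 19 pathway lists and 5 lists of marker genes of other cell types were fixed from textbook knowledge, together with the main tests and the alternatives. They hold 598 different genes, of which 548 were measured, 14 of them under an older symbol, and the remaining members were not analysed here. Each list was tested with camera at its preset inter-gene correlation of 0.01, which asks whether members rank higher or lower than the other genes, with adjustment over the 24 lists. The same lists were tested with a correlation estimated from the data and with fry, which asks whether members move on balance in one direction. With an estimated correlation camera rests on the residual degrees of freedom, few here and fewer with the block or with arrays left out. A call lost there is therefore weak evidence against a shift. Members were also adjusted over the list alone. Genes named in the text are Angpt2, Tek, Tie1, Angpt1, Mcph1 and Agpat5, up to 10 called genes in each direction, and for each list its called members or, with no called member, the member with the largest absolute log2 fold change. Any other gene named was chosen after its values were seen.

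Both groups share the replicate numbers 1, 2 and 3. Whether the numbers pair the arrays was checked from the data, since the labels do not say that a number marks a shared day. Deviations from the group means correlated across genes at 0.13, 0.21 and 0.14 for arrays with the same number, and each array correlated best with its own number in the other group. With 3 arrays per group such a match can also arise by chance, so the pairing is not established. The numbers were treated as pairs on this basis, and the fit with the number as a block is given where it changed a call. The main fit has no block, as fixed in advance.

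Alternatives were the block, quantile normalization, centring each array on its median, 2 filters on dim genes (above the median or above the 33rd percentile of level), the mean of all clusters of a gene, all 40425 complete clusters instead of named genes, eBayes with trend and robust options, array weights, pseudocounts of 1 and 16, leaving out each array in turn, and the other set tests. Control probes could not be identified from the annotation used, so the setting with all clusters includes any that carry a value. The block together with an estimated correlation, the fits with both arrays of a replicate number left out, and an estimated correlation in the fits with arrays left out were added after seeing the data.

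The fit was tested on simulated data with independent noise and the spread of the 22180 genes as moderated by eBayes. That spread varies less between genes than the observed one, so the shares called may be too high. With 10 genes changed per simulation over 50 simulations, it called 22.2% of 1.5-fold changes, 98% of 2-fold changes and 100% of 4-fold changes. For a list of 17 genes with no shift whose members shared a random effect of each culture, camera gave an unadjusted p under 0.05 in 67% of 100 simulations at the preset correlation and in 14% with an estimated one. Lists shifted by 0.15 on the log2 scale with independent members had an unadjusted p under 0.05 in 100% and 94%. Calls in the results use p adjusted over all lists, which is stricter, so these shares are not the detection rate of such calls. In the data the mean log2 fold change was 0.076 for respiratory chain, 0.069 for cytokine and 0.056 for cell cycle genes. It was 0.15 for cholesterol synthesis genes. Detection of the smaller shifts, or of shifts with correlated members, was not simulated. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.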

Results

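Gene expression was profiled in RET mouse melanoma cells with a non-targeting control shRNA (3 cultures) and in the same line with 1 shRNA against Angpt2, called Angpt2 shRNA-1 (3 cultures). Angpt2 encodes angiopoietin-2, a secreted ligand of the endothelial receptor Tek (Tie2). The cells were grown for 24 h in standard medium, and the comparison asks what silencing of Angpt2 does to the transcripts of the tumour cells themselves. The samples hold no other hairpin and no rescue. Effects of Angpt2 loss therefore cannot be told from other effects of this hairpin or from differences between the 2 sets of cells. Cells with this shRNA are called silenced cells below. Normalized array intensities were available for 22180 named genes. Array medians over all clusters ranged from 74.5 to 76.2.

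Angpt2 transcript (gene ID 11601, transcript cluster 17507799) was lower on every Angpt2 shRNA-1 array than on any control array. Its intensity was 195, 372 and 326 on control replicates 1, 2 and 3, and 100.2, 122 and 122 on the corresponding Angpt2 shRNA-1 arrays. On the log2 scale this was 8.17 ± 0.49 in controls against 6.84 ± 0.17 in Angpt2 shRNA-1 cells (SD, n = 3 arrays each), a log2 fold change of -1.33 (SE 0.21, 95% confidence interval -1.81 to -0.85) or 2.51-fold lower. Within replicate numbers 1, 2 and 3, with 1 array per group in each, the log2 differences were -0.96, -1.60 and -1.42.

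By unadjusted limma p, 1.425e-04, Angpt2 ranked number 3 of 22180 genes, but the adjusted p over all genes was 1.00, so the reduction did not pass the threshold across the transcriptome. Adjusted over the list alone, among 23 angiopoietin and vascular growth factor genes, Angpt2 passed with a limma adjusted p = 0.00328. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 arrays can give. With the replicate number as a block the adjusted p over all genes was 0.046, and without control replicate 1, the control array with the least Angpt2, the log2 fold change was -1.61 with adjusted p = 0.0116. On replicates 1 and 2 alone, with 2 arrays per group, the limma adjusted p over the list alone was 0.0838.

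Transcripts of the related ligand and of the receptors were not called. Log2 fold changes were -0.16 (SE 0.11) for Angpt1, the other main Tek ligand, 0.08 (SE 0.09) for Tek and -0.02 (SE 0.10) for Tie1, the Tek co-receptor. Without detection calls, the dim signals of Tek (intensity 54.9 to 66.0 over the 6 arrays), Tie1 (65.7 to 83.1) and Angpt1 (50.9 to 71.1) cannot be told from background. A dimmer Angpt1 cluster gave 0.08. Without control replicate 1 Angpt1 was at -0.05. Mcph1, a gene of the DNA damage response whose span contains Angpt2 in the RefSeq annotation, was at 0.10 (SE 0.10), and the neighbouring acyltransferase gene Agpat5 at 0.01 (SE 0.12). None of the 5 passed the test, each with adjusted p = 1.00.

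**Figure D1:**
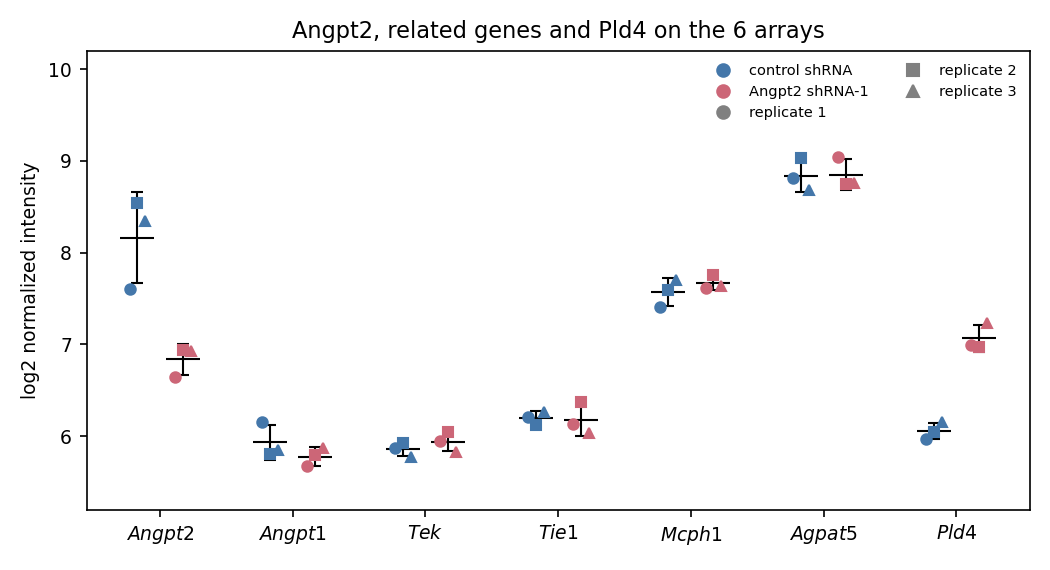
Log2 normalized intensity (vertical axis) of 7 genes on the 3 control shRNA arrays (blue) and the 3 Angpt2 shRNA-1 arrays (red), with marker shape giving the replicate number and black bars the mean ± SD (n = 3). The Angpt2 values of the silenced cells, 6.65 to 6.94, all lie below those of the controls, 7.61 to 8.54, and the Pld4 values of the silenced cells all lie above the controls.

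Beyond Angpt2, 4 genes differed by at least 2-fold in group means, and they were singled out after their values were seen. Pld4, an endolysosomal nuclease of the phospholipase D family, was 2.01-fold higher (log2 6.06 ± 0.09 in controls, 7.07 ± 0.14 in silenced cells, SD, n = 3; log2 fold change 1.01, SE 0.10, limma adjusted p = 0.0672). Its difference was 1.02, 0.92 and 1.08 in replicates 1, 2 and 3. The control intensities of Pld4, 62.6, 66.3 and 71.0, cannot be told from background, so the fold is that of the signals. Kpna2, an importin alpha that carries proteins into the nucleus, was at a log2 fold change of 1.04 (SE 0.33), Tmed2, a cargo receptor of early secretory vesicles, at 1.02 (SE 0.37), and Btbd35f12 at -1.14 (SE 0.37), each with adjusted p = 1.00. In replicates 1, 2 and 3 the difference of Kpna2 was 1.40, 1.78 and -0.07, that of Tmed2 0.95, 0.75 and 1.35, and that of Btbd35f12 -1.79, -0.13 and -1.51. Zfp980, a zinc finger gene, ranked number 2 by p at -0.78 (SE 0.11, limma adjusted p = 0.482). Its intensities, 40.6 to 86.5 over the 6 arrays, cannot be told from background. The same holds for Btbd35f12 on the silenced arrays (59.6 to 74.4) and on control replicate 2 (68.8).

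No gene passed the threshold. The limma fit called 0 genes higher and 0 lower at an adjusted p of 0.05, against 835 at an unadjusted p under 0.05 (338 higher, 497 lower), where chance alone gives 1109. The balance of these directions depended on scaling and arrays, with 413 higher and 402 lower after quantile normalization, 161 and 169 above the median level, 495 and 505 without control replicate 1, and 375 and 364 on replicates 2 and 3 alone. Without control replicate 3 the number was 1274. The arrays of both groups did not overlap for 9.01% of genes, against 10% by chance. With the replicate number as a block, 2 genes passed, Angpt2 and Pld4, each with adjusted p = 0.046. For the median gene the 95% interval reached 0.23 on the log2 scale, or 1.17-fold, to each side of its estimate. Without control replicate 2, Btbd35f12 (-1.68, adjusted p = 0.0129) and Plekho1 (1.18, adjusted p = 0.0196) passed, and without control replicate 1 Angpt2 alone did.

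**Figure D2:**
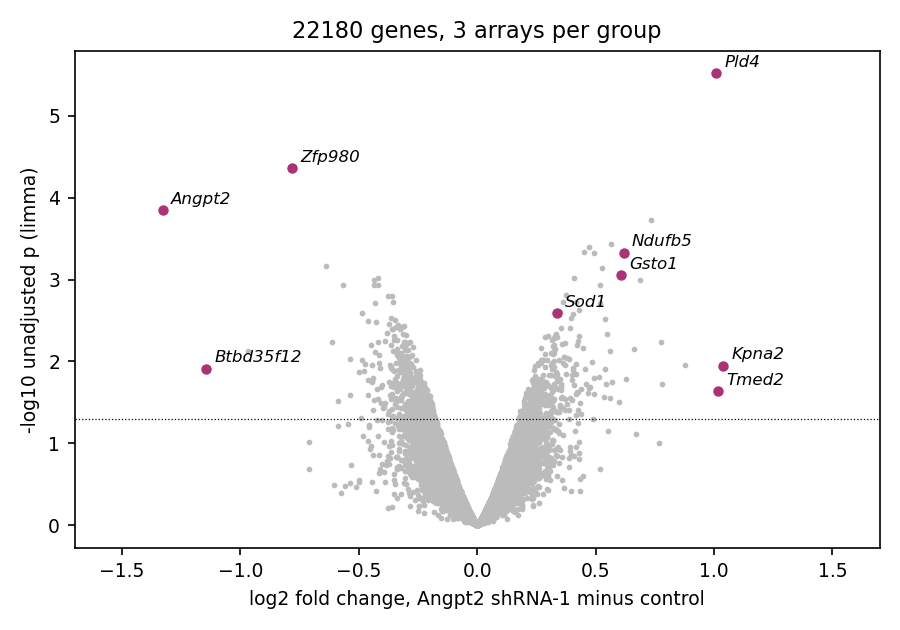
Log2 fold change of Angpt2 shRNA-1 over control shRNA (horizontal axis) against minus log10 of the unadjusted limma p (vertical axis) for 22180 genes, 1 grey point per gene, with the dotted line at an unadjusted 0.05 and 9 genes marked in purple. Pld4, Zfp980 and Angpt2 have the lowest p-values, and no gene passes an adjusted p of 0.05.

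Genes of mitochondrial respiration ranked higher in the silenced cells as a list at the preset correlation, by small amounts, and not with an estimated correlation (adjusted p = 0.916). Of 69 measured nuclear-encoded subunits of the respiratory chain and ATP synthase, 53 had positive log2 fold changes, with a median of 0.05 (camera adjusted p = 3.47e-04). Within replicates 1, 2 and 3 their median difference was -0.01, 0.18 and 0.02. Ndufb5, a complex I subunit, was 1.54-fold higher (0.62, SE 0.12), above the controls on all 3 arrays, and the only member to pass when adjusted over the list alone (limma adjusted p = 0.0322). Over all genes 0 members passed. The complex I subunits Ndufc1 (0.57, SE 0.20) and Ndufb3 (0.33, SE 0.16) and the ATP synthase gene Atp5g3 (0.23, SE 0.11) had positive values that passed neither test, with Ndufb3 at 0.14 without Angpt2 shRNA-1 replicate 3. The list's call was also lost without control replicate 2 (adjusted p = 0.416), the array on which these genes had their lowest median deviation from the mean of the 6 arrays, -0.12, and on replicates 1 and 3 alone (adjusted p = 0.491).

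Cholesterol synthesis genes also ranked higher at the preset correlation and not with an estimated one (adjusted p = 0.916). Of 17 measured members 15 were positive, with a median log2 fold change of 0.16 (camera adjusted p = 4.51e-04), among them Fdps, which makes farnesyl diphosphate (0.31, SE 0.20), Dhcr7, the enzyme of the last step to cholesterol (0.29, SE 0.14), and Hmgcs1 (0.27, SE 0.18). Without control replicate 2 Fdps was at 0.08, and without control replicate 1 Dhcr7 was at 0.14 and Hmgcs1 at 0.05. No member passed over all genes or over the list alone. Without control replicate 1 the adjusted p was 0.617, without Angpt2 shRNA-1 replicate 3 it was 0.144, with array weights 0.125 and on replicates 2 and 3 alone 0.624. The list's median deviation was lowest on control replicate 1 (-0.28) and highest on Angpt2 shRNA-1 replicate 3 (0.22), with control replicate 3 also high (0.14).

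Of 27 cytokine and chemokine genes, 21 were positive with a median log2 fold change of 0.05 (camera adjusted p = 0.00837, and adjusted p = 0.762 with an estimated correlation). Mif, an abundant secreted inflammatory factor, was at 0.33 (SE 0.16), the monocyte chemokine Ccl7 at 0.24 (SE 0.15) and Cxcl12 at 0.23 (SE 0.10), while Tgfb1 was at -0.23 (SE 0.17), and 0 members passed over all genes or over the list alone. Without control replicate 2 Mif was at 0.13, and without control replicate 1 Ccl7 was at 0.10 and Tgfb1 at -0.01. The intensities of Cxcl12, 54.2 to 73.5, and of Ccl7, 62.3 to 96.8, cannot be told from background. The list's adjusted p was 0.0745 without control replicate 2, 0.0841 without Angpt2 shRNA-1 replicate 3 and 0.154 on replicates 2 and 3 alone. Restricted to genes above the median level it was 0.238, and above the 33rd percentile 0.0806.

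Cell cycle and DNA replication genes were positive for 23 of 32 members, with a median log2 fold change of 0.04 (camera adjusted p = 0.0259, and adjusted p = 0.916 with an estimated correlation). Tyms, the thymidylate synthase, was at 0.39 (SE 0.16), Ccne1, which encodes cyclin E, at 0.24 (SE 0.15) and the mitotic kinase gene Aurka at 0.21 (SE 0.11), and 0 members passed over all genes or over the list alone. The call was also lost with quantile normalization (adjusted p = 0.0860), above the median level (0.0532), above the 33rd percentile (0.0567), with array weights (0.292) and without Angpt2 shRNA-1 replicate 2 (0.491). Without control replicate 1, where the list's median deviation was -0.24 against -0.02 to 0.09 on the other arrays, its direction turned and it was not called (adjusted p = 0.596), with Tyms at 0.18, Ccne1 at 0.13 and Aurka at 0.13.

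These 4 lists were those called among 24, all toward higher expression. With an estimated correlation or with fry 0 lists were called, the lowest adjusted p being 0.762 and 0.815. The test with an estimated correlation rests on few residual degrees of freedom and allows for members that move together. In the self-test it gave an unadjusted p under 0.05 for 94% of lists shifted by 0.15 with independent members. Cholesterol synthesis genes had a mean log2 fold change of 0.15 but an estimated correlation of 0.616. Their unadjusted camera p with that correlation was 0.249. Detection of smaller shifts was not simulated. With the replicate number as a block, 2 further lists passed at the preset correlation, and both are given next.

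Melanocyte differentiation and pigmentation genes were negative for 17 of 21 members, with a median log2 fold change of -0.09 (camera adjusted p = 0.0698, and 0.0444 with the block). With the block and an estimated correlation the adjusted p was 0.977. Slc24a4, an ion exchanger gene, was at -0.34 (SE 0.21), Mitf, the master regulator of the lineage, at -0.20 (SE 0.08), and the pigment enzyme gene Tyr at -0.15 (SE 0.20). Control replicate 1 carried the values of Slc24a4 and Tyr, which were -0.05 and 0.12 without it, and within replicates 1, 2 and 3 the difference of Slc24a4 was -1.07, -0.09 and 0.13. The list's median deviation was highest on control replicate 1 (0.13), and without that array its adjusted p was 0.989. The list was called toward lower expression without control replicate 3 (0.00609), without Angpt2 shRNA-1 replicate 1 (0.0129), with quantile normalization (0.0419), with trend and robust options (0.0342) and with a pseudocount of 16 (0.0466). With an estimated correlation it was not called in any fit that left out an array. Glycolysis genes were positive for 16 of 19 members, with a median of 0.05 (camera adjusted p = 0.0884, and 0.0183 with the block). With the block and an estimated correlation the adjusted p was again 0.977. Pfkfb3, which makes the activator of phosphofructokinase, was at 0.26 (SE 0.21) and Hk2, a hexokinase gene, at 0.22 (SE 0.25), and 0 members of either list passed over all genes or over the list alone. Hk2 was at -0.03 without control replicate 1 and at -0.01 without Angpt2 shRNA-1 replicate 3, and the difference of Pfkfb3 within replicates 1, 2 and 3 was 0.30, 0.47 and -0.01. The median deviation of glycolysis genes stood apart on Angpt2 shRNA-1 replicate 3 (0.35, with control replicate 3 at 0.13 and the other 4 arrays between -0.15 and -0.03), as did that of hypoxia genes. Within replicates 1, 2 and 3 the median difference of glycolysis genes was 0.02, 0.04 and 0.10, and without Angpt2 shRNA-1 replicate 3 the direction turned (adjusted p = 0.915). The list was called toward higher expression without control replicate 3 (0.00422), without Angpt2 shRNA-1 replicate 1 (0.0129), without Angpt2 shRNA-1 replicate 2 (0.00331) and with the mean of all clusters of a gene (0.0493). With an estimated correlation the adjusted p without these 3 arrays was 0.805, 0.902 and 0.849.

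Genes that handle reactive oxygen went in both directions. Of 22 genes for peroxide and superoxide removal, 14 were positive (median log2 fold change 0.06, camera adjusted p = 0.442). Without control replicate 3 the list was called toward higher expression (adjusted p = 0.0296, and adjusted p = 0.757 with an estimated correlation), as it was on replicates 1 and 2 alone (0.0436, and 0.917 with an estimated correlation). Txn2, the mitochondrial thioredoxin, was 1.53-fold lower (-0.61, SE 0.17) and Sod1, the cytosolic superoxide dismutase, was at 0.34 (SE 0.08; limma adjusted p = 0.0566 when adjusted over the list alone), while the glutathione peroxidase gene Gpx4 was at -0.29 (SE 0.13). Of 22 NRF2 target genes, 16 were negative (median -0.06, camera adjusted p = 0.610), and the cystine transporter gene Slc7a11 was at -0.61 (SE 0.58), with an intensity of 1184 on control replicate 1 against 166 to 327 on the other 5 arrays and a value of 0.20 without that array. Among 26 genes of mitochondrial dynamics, biogenesis and mitophagy 16 were negative (median -0.02, adjusted p = 0.901), and the mitophagy receptor gene Fundc1 was at -0.46 (SE 0.16). Without Angpt2 shRNA-1 replicate 1 Txn2 was at -0.39 and Fundc1 at -0.29, and without control replicate 2 Gpx4 was at -0.14. None of these genes passed over all genes or over its list alone.

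Stress and signalling lists were not called by camera on the full set of arrays. The unfolded protein and integrated stress response list was negative for 16 of 28 members (median log2 fold change -0.05, adjusted p = 0.901), and the chaperone gene Hspa5 was at 0.55 (SE 0.27) while Ddit3, which encodes CHOP, was at -0.51 (SE 0.51). Control replicate 1 had this list's highest median deviation, 0.57 against -0.34 to 0.06 on the other 5 arrays, and without that array the list was called toward higher expression (adjusted p = 6.66e-04, and adjusted p = 0.989 with an estimated correlation). With both replicate 1 arrays left out it was not called (adjusted p = 0.103). Without control replicate 1 Hspa5 was at 0.21 and Ddit3 at 0.17. Hypoxia response genes were negative for 11 of 20 members (median -0.05, adjusted p = 0.901), with Vegfa at -0.29 (SE 0.33), at -0.04 without control replicate 1 and at -0.65 without Angpt2 shRNA-1 replicate 3. Without Angpt2 shRNA-1 replicate 3, which had their highest median deviation (0.37), they were called toward lower expression (adjusted p = 1.55e-04, and adjusted p = 0.952 with an estimated correlation). Control replicate 3 was also high (0.21), and with both replicate 3 arrays left out the list was not called (adjusted p = 0.0812).

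P53 target genes were positive for 11 of 22 members (median 0.01, camera adjusted p = 0.901), and Rrm2b, a subunit of ribonucleotide reductase, was at -0.46 (SE 0.12; limma adjusted p = 0.0714 when adjusted over the list alone). Apoptosis genes were positive for 13 of 24 (adjusted p = 0.901), with Casp6 at 0.36 (SE 0.23), at 0.17 without control replicate 1 and at 0.64 without control replicate 3. Immediate early and MAPK output genes were negative for 18 of 29 (median -0.03, adjusted p = 0.995), with Etv5, an ETS factor gene downstream of ERK, at 0.29 (SE 0.31). Genes of the dedifferentiated or invasive melanoma state were negative for 10 of 18 (median -0.02, adjusted p = 0.901), with Thbs1, which encodes thrombospondin-1, at 0.30 (SE 0.21). The values of Etv5 and Thbs1 came from control replicate 1 and were -0.03 and 0.02 without it. Within replicates 1, 2 and 3 the difference of Etv5 was 0.95, -0.04 and -0.03, and that of Thbs1 0.80, -0.01 and 0.10.

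Among immune and matrix genes, type I interferon response genes were positive for 18 of 27 members (median 0.03, camera adjusted p = 0.442; Ifit2 0.32, SE 0.17). MHC class I presentation genes were positive for 7 of 14 (adjusted p = 0.901; the proteasome activator gene Psme1 0.26, SE 0.12), and genes of extracellular matrix, adhesion and proteases for 25 of 48 (adjusted p = 0.789; the metalloproteinase inhibitor gene Timp3 -0.33, SE 0.19). Timp3 rested on control replicate 1, with differences of -0.97, -0.19 and 0.17 within replicates 1, 2 and 3 and a value of -0.10 without that array. Without control replicate 2 Ifit2 was at 0.13 and Psme1 at 0.12. The angiopoietin and vascular growth factor list itself was negative for 12 of 23 members (adjusted p = 0.901).

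Marker genes of other cell types gave no called list. Endothelial markers were negative for 7 of 12 (camera adjusted p = 0.919; Cdh5 0.23, SE 0.20), haematopoietic markers positive for 6 of 11 (0.901; Fcer1g -0.17, SE 0.16), and fibroblast and mural markers positive for 6 of 12 (0.901; Pdgfrb 0.16, SE 0.09). Epithelial markers were negative for 8 of 11 (0.565; Epcam -0.32, SE 0.10) and Schwann cell and glial markers for 5 of 8 (0.821; Erbb3 -0.22, SE 0.11). Cdh5 was at 0.06 without control replicate 2, Fcer1g at -0.02 without control replicate 1 and Erbb3 at -0.13 without Angpt2 shRNA-1 replicate 1. The intensities of Cdh5 (50.3 to 90.9) and Epcam (46.1 to 68.9) cannot be told from background. Apart from Angpt2 and Ndufb5, 0 members of the 24 lists passed when adjusted over their list alone. Camera compares members with other genes, and its direction was upward although the median was negative for the stress response, mitochondrial dynamics, immediate early, dedifferentiated state and MHC class I lists; the mean was negative for the first 3 and positive for the others. For the haematopoietic markers the test and the median were positive and the mean was slightly negative.

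**Figure D3:**
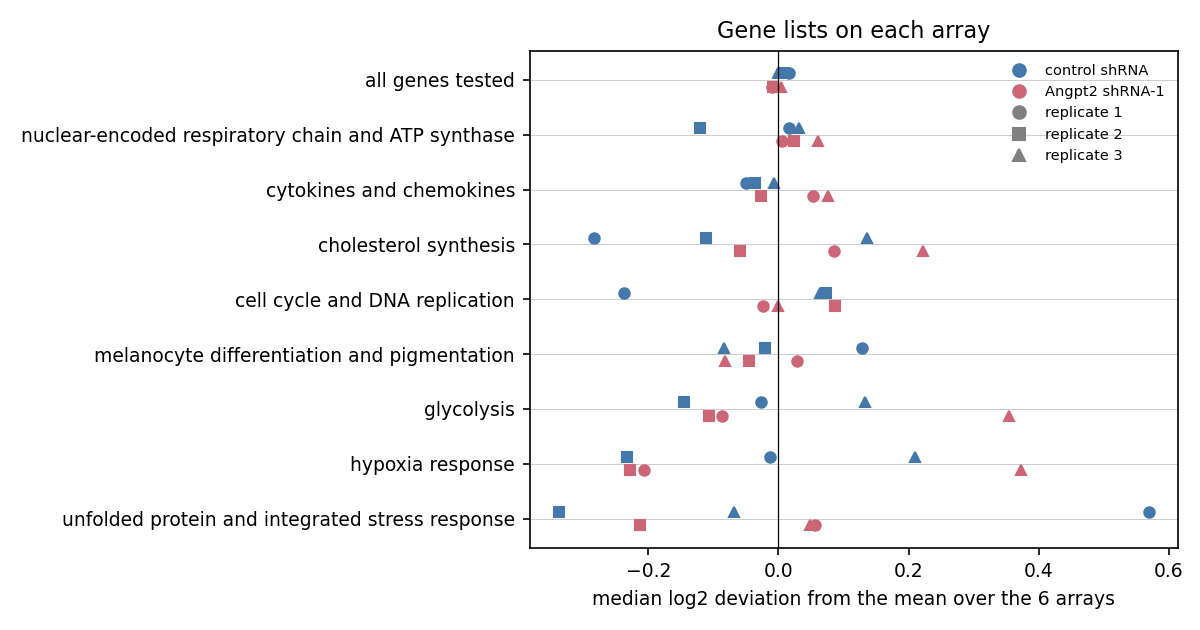
Median over list members of the log2 deviation from the mean of the 6 arrays (horizontal axis), for all genes and 8 gene lists, on control shRNA (blue) and Angpt2 shRNA-1 arrays (red), with marker shape giving the replicate number. Stress response genes stand at 0.57 on control replicate 1, and hypoxia genes at 0.21 and 0.37 on both replicate 3 arrays.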

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

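The Angpt2 log2 fold change was negative under all alternatives. It was -1.33 (adjusted p = 0.046) with the replicate number as a block, -1.51 (adjusted p = 0.0404) on replicates 2 and 3 alone, and -1.61 to -1.14 when single arrays were left out, of which only leaving out control replicate 1 gave a call. Its adjusted p ran from 0.0116 to 1.00 over the alternatives, and from 1.199e-05 to 0.0838 when adjusted over the list alone, the highest on replicates 1 and 2 alone. The number of genes changed, and of those changed at least 2-fold, was 2 with the block, 1 with trend and robust options (Pld4, adjusted p = 0.0372), 1 on replicates 2 and 3 alone (Angpt2), and 0 to 2 when single arrays were left out. It was 0 under the other alternatives. The number of gene lists shifted was 2 above the median level, 2 above the 33rd percentile, 2 with array weights and 1 on replicates 2 and 3 alone (respiratory chain). It was 0 with an estimated correlation, 0 with fry, 0 with the block and an estimated correlation together, and 2 to 7 when single arrays were left out. With an estimated correlation 0 lists were called whichever array or replicate pair was left out. That outcome rests in part on the few residual degrees of freedom in these fits. Members that move together also count. On all 6 arrays the estimated correlation was 0.616 for cholesterol synthesis, 0.485 for cell cycle and 0.176 for respiratory chain genes. For these lists the calls at the preset correlation of 0.01 therefore count for less. For cytokine genes it was 0.0112, so there the lost call does not argue against the list. The cell cycle list turned to the negative side, uncalled, on replicates 2 and 3 alone (adjusted p = 0.927) and without control replicate 1, its adjusted p ranging from 4.199e-04 to 0.596 when single arrays were left out. In each case the cause was not tested, except that the filters and the fits with arrays left out use fewer genes or arrays. The block changed no call other than those of Angpt2, Pld4, melanocyte and glycolysis genes. Over all combinations of a gene list and an alternative, 487 kept their side of the threshold, 15 gained a call, 24 lost one and 2 turned. For the named genes in the tally 741 kept theirs and 5 gained a call, with directions compared only where a value was called. The tally leaves out Btbd35f12 and Plekho1, which each gained a call without control replicate 2. With independent noise and 10 changed genes the self-test called 98% of simulated 2-fold and 22.2% of 1.5-fold changes, and with more changed genes 100% and 83.6%. Angpt2, 2.51-fold lower with a wider spread between controls, was not called in the main fit of the real data. Pld4, 2.01-fold higher with an SE of 0.10, like the median SE of all genes, was not called there either. The simulated spread, moderated by eBayes, varies less between genes than the observed one, so the self-test may overstate detection. Without detection calls, the signal over background that dim genes carry is not known.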

Other observations

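The gene families below, and the tests of array scale and of other cell types for control replicate 1, were chosen after the results were seen. Mitochondrial ribosomal protein genes, which serve translation inside mitochondria, were positive for 49 of 71 members (median log2 fold change 0.03, camera adjusted p = 0.00618 over 12 families, and 0.717 with an estimated correlation). Their median deviation was lowest on control replicate 2 (-0.05), while control replicate 3 (0.03) was level with the silenced arrays (0.02 to 0.04). Cytosolic ribosomal protein genes were positive for 42 of 67 (adjusted p = 0.161), proteasome genes for 24 of 39 (0.349) and genes of V-ATPase, the proton pump of lysosomes, for 6 of 22 (0.474). Among genes with low unadjusted limma p, Gsto1, a glutathione transferase, was at 0.61 (SE 0.13), Spr, which makes tetrahydrobiopterin, at 0.47 (SE 0.09), and G3bp1, a stress granule protein, at 0.53 (SE 0.11). Each had adjusted p = 1.00, and all 3 silenced arrays lay above the controls. Hypoxia response genes had median deviations of -0.01, -0.23 and 0.21 on control replicates 1 to 3 and -0.21, -0.23 and 0.37 on the silenced arrays, and the carbonic anhydrase gene Car9 was highest on Angpt2 shRNA-1 replicate 3 (log2 7.87 against 6.64 to 7.23).

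The real split of the 6 arrays called 0 genes and 4 gene lists by camera at its preset correlation. The 10 splits are too few for a share under 0.05, with at most 1 gene and 8 lists in any other split. The 3 other splits that part all 3 replicate pairs, as the real one does, called 0 genes and 4, 1 and 2 lists (median 2), while the 6 splits that part 1 pair, and so also carry differences between pairs, called up to 1 gene and 2 to 8 lists. The median over these 9 splits was 4 lists, so list members that move together between cultures of one group may account for part or all of the calls. With an estimated correlation 0 lists were called in each, which cannot decide this alone, as that test also rests on few residual degrees of freedom. The estimated correlation itself was 0.616 for cholesterol synthesis, 0.485 for cell cycle and 0.176 for respiratory chain genes. Members of these lists thus moved together between arrays of one group. For cytokine genes the estimated correlation was 0.0112, near the preset 0.01, yet the unadjusted camera p rose from 0.00105 to 0.0317. For that list the lost call does not show shared movement. With the replicate number as a block the real split gave 2 genes and 6 lists, and 0 lists with the block and an estimated correlation.

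Control replicate 1 stood apart, with 65 genes at least 2-fold from the mean of the other 5 arrays against 10 to 21 for the others. Of 28 stress response genes 17 were highest there and 11 at least 2-fold higher, including Nupr1 (5.88-fold above the mean of the others), Trib3 (4.43-fold), Ddit3 (3.87-fold) and Chac1 (3.59-fold), whereas the endoplasmic reticulum chaperone gene Hspa5 was 2.23-fold lower. An array scale that acts alike on genes of one level keeps their order. It is argued against by the list's median change of percentile rank on that array. This was 1.66 points against at most 0.708 in 10000 random lists matched on level. Cells of another type are not settled by the 5 marker lists, whose highest deviation there was 0.0869, against 0.569 for the stress list. How far such markers would move is not known. Schwann cell, haematopoietic and fibroblast markers had their highest median deviation on that array, while endothelial and epithelial markers did not. An amino acid or ATF4-type stress in that culture is a candidate explanation: 18 cytosolic aminoacyl-tRNA synthetase genes, none in the list, had a median deviation of 0.401 there, against at most 0.0141 on the other arrays, above all 10000 random lists matched on level. The labels name no difference between this culture and the other controls, and what set off such a response was not tested.

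Small nucleolar RNA genes were low on replicate 1 of both groups. Snora34, where it was first seen, was at log2 8.50 and 8.56 there and 9.89 to 10.3 on the other 4 arrays. The other 77 had median deviations of -0.38 and -0.21 there against 0.08 to 0.30, and 56 (72.7%) had both replicate 1 arrays lowest, against 8.07% of all genes and 6.67% by chance. The pattern was picked as one shared by both groups, so the groups' means are no separate test of Angpt2 silencing. Their difference was -0.0200, beside -0.437 between replicate 1 and the rest. RNA preparation shared by arrays with one replicate number may account for the pattern. The higher of both replicate 1 medians, -0.211, is below the other arrays. This extends the pattern to the other 77 genes but does not single out that cause. The preparation dates that would test it further were not used here.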
